A study of Sus scrofa with 16 samples.

How the data were processed

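Gene expression was measured in the subcutaneous adipose tissue of 16 pigs at 20 kg body weight, 8 of the low-RFI line and 8 of the high-RFI line, with 1 Agilent 1-colour array per pig. Per the labels' protocols, RNA was isolated with Trizol and silica columns, and 150 ng of total RNA per pig was amplified and labelled with Cy3. Per the file headers, the arrays were scanned and quantified with Agilent Feature Extraction 10.7.3.1. The signals read here were the deposited processed intensities, which per the file headers had been background subtracted and detrended within each array by that software and had not been normalised between arrays. The deposited mean and local background intensities of each spot, also per the file headers, carried no correction. A value table was deposited as well. Its log2 values were checked against the scanner files: on each array they equalled the log2 processed signal minus the median over the 28963 spots that the deposited table lists (Pearson r = 1.0 across spots, column median 0). R 2.10.0 is named in the submitters' processing notes, and how the listed spots were chosen is not stated.

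Each array held 45220 spots, of which 43803 were not controls. They made up 43603 probes, 50 of them spotted 5 times. Spots marked as outliers by the scanner software were left out, which left 610 values missing among the probes kept (0.119%), and the remaining spots of a probe were averaged. The log2 of the processed signal minus the array's 75th percentile was used, so a value of 0 is the 75th percentile of that array. A probe was kept if it was well above background on at least 8 of the 16 arrays, counted without regard to line. It also needed at least 6 values in each line, a condition added after the outlier spots had been seen, which took the 32216 probes to 32097. The share of spots well above background was 74.1% on average (SD 3.29, n = 16 arrays), and no spot was saturated. The number of arrays limits the precision.

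No probe annotation came with the arrays beyond the names in the scanner files. Symbols were taken from those names, from gene IDs in the files, or from RefSeq accessions looked up in the gene table of the Sscrofa11.1 assembly, used for names only. In this way 12164 probes received 5334 symbols. The names in the files and the accession pointed to different genes for 71 named probes. No gene name was found for 30593 probes and a LOC name only for 846, so 21394 of the kept probes entered the probe count but no gene or list. A gene was represented by its kept probe with the highest mean signal over all arrays, which gave 4631 genes.

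The lines were compared with limma 3.58.1 in R 4.3.3 (linear model with line as the only term and moderated statistics, two-sided). Benjamini-Hochberg adjustment ran over probes, over genes and over gene lists, with a threshold of 0.05. Differences are log2, low-RFI minus high-RFI, with the model's standard error (SE). Before the data were examined, 39 gene lists of adipose, energy, stress, immune and cell type marker genes were fixed. They hold 998 entries, of which 533 were measured. The 36 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry were the alternatives. Camera compares a list with all other genes, and fry tests whether the genes of a list move on balance in 1 direction. The rule for named genes was also fixed beforehand. Among genes past the threshold it takes the 12 largest differences in each direction. If fewer than 10 genes pass, it takes the 10 with the smallest p as values only. From each list it takes up to 3 passing members per direction, or, if none passes, the 2 members with the smallest p as values only. Genes well above background in 1 line alone were to be given as at least N-fold, up to 5 per direction among passing genes, and none passed. Some genes that the rule picks are not reported here, without replacement, and the list tests include them. Genes named outside this rule are marked as chosen after their values were seen.

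The procedure was tested on simulated data with the means and spreads of these 16 arrays. Of 67, 67 and 66 probes changed 1.5-, 2- and 4-fold, 41.8%, 74.6% and 93.9% were recovered among 32097, with 6 unchanged probes called. Of as many changed genes, 46.3%, 79.1% and 92.4% were recovered among 4631, with 8 unchanged genes called. The share recovered depends on how many are changed, which is not known for the lines, so it is not the power of the real comparison. Both lists shifted by 0.3 log2 were called by camera with the preset correlation, by camera with an estimated correlation and by fry, with 1, 0 and 1 unchanged lists called. The simulated noise was independent between genes, so it does not show how the list tests behave when genes of a list are correlated. In the data the estimated correlation between genes was 0.63 for oxidative phosphorylation and 0.80 for skeletal muscle.

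The scanner files assigned the arrays to 4 slides, each with 2 arrays of each line, and each slide was 1 scan. The fit was repeated with slide as a term and within each slide. Alternatives fixed beforehand covered background correction (normexp, offset 50), quantile and median scaling, the deposited value table, the filter on dim probes, array weights, the variance prior, the threshold, the probe that stands for a gene, a replicate block, a slide block and leaving out each array. Fits without 4 arrays, with a sample set block, with set and slide, and within replicates 1 to 4 or 5 to 8 were added after the data were seen. A sample set is replicates 1 to 4 or 5 to 8 of both lines. The deposited scanner files number these samples in separate runs, and what the numbers stand for is not given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.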

Results

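Subcutaneous adipose tissue was sampled from 16 pigs at 20 kg body weight that were fed freely. Of these, 8 came from a line selected for low residual feed intake (low-RFI) and 8 from a line selected for high residual feed intake (high-RFI). Residual feed intake is the part of feed intake not explained by growth and maintenance, so low-RFI pigs eat less than predicted for their performance. RNA from each pig was read on 1 array. Between 68.7% and 80.3% of the spots were well above background, with a mean of 74.6% (SD 2.36, n = 8) in low-RFI and 73.6% (SD 4.14, n = 8) in high-RFI pigs. Correlation between pairs of arrays, across probes, ranged from 0.944 to 0.989. The comparison of the lines asks how selection on feed efficiency is reflected in the transcripts of fat tissue.

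No single gene separated the lines, and the 10 genes closest to a difference were 1.28- to 2.01-fold apart. MAB21L1, a developmental regulator, had a signal of -2.74 ± 0.32 (SD, n = 8) in low-RFI and -3.62 ± 0.44 (SD, n = 8) in high-RFI pigs, a difference of 0.88 (SE 0.18). DKK3, a secreted protein of the dickkopf family, differed by 1.01 (SE 0.27). CYR61, a matricellular protein, differed by 0.75 (SE 0.19) and ADM, which encodes the vasodilator peptide adrenomedullin, by 0.57 (SE 0.16). SLC5A4, a member of the sodium and glucose cotransporter family, differed by -0.66 (SE 0.16), with the higher signal in high-RFI pigs. None of these passed the threshold, and the smallest adjusted p over the 4631 genes was 0.838 in limma.

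In limma, 0 of 32097 probes and 0 of 4631 genes differed at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1181 probes (568 higher and 613 lower in low-RFI pigs), against 1605 by chance alone, and 177 genes (72 higher and 105 lower), against 232. The median absolute difference of a gene was 0.10, and the 95% interval of a gene's difference reached 0.31 to either side at the median. That interval excluded a 2-fold difference in either direction for 4109 genes (88.7%) and a 1.5-fold difference for 3214 (69.4%). Without low-RFI replicate 4, 1 probe with no gene name passed in limma, at -2.77 (adjusted p = 0.0126). Over 32 alternative fits no gene passed, and array weights gave the most probes at an unadjusted p under 0.05, 2154. With slide as a block 0 probes and 0 genes passed in limma, with 1244 probes at an unadjusted p under 0.05. Within slides 1 to 4 there were 0 probes each in limma (614, 795, 1493 and 772 at an unadjusted p under 0.05).

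The other genes among the 10 with the smallest p were RARB, a retinoic acid receptor, at 0.61 (SE 0.16), RAB6B, a GTPase of Golgi traffic, at 0.83 (SE 0.22), PLOD2, a collagen lysyl hydroxylase, at 0.36 (SE 0.11), CLC-2, a chloride channel, at -0.44 (SE 0.13), and SCT at -0.84 (SE 0.19). The accession of the SCT probe names secretin, whereas its description in the files names a cadherin-related protein, so its identity is uncertain. All 10 genes kept the sign of their difference with slide as a block and within each of the 4 slides. MAB21L1, for instance, differed by 0.88 with the block and by 0.73, 0.61, 0.996 and 1.19 within the slides. The low-RFI value lay on the same side of the high-RFI mean in 8 of 8 pigs for 8 of these genes and in 7 of 8 for DKK3 and CLC-2. The genes were picked for a small p on these same arrays, so such agreement is favoured by the choice and adds no support. With 2 arrays of each line on every slide, the block leaves a difference unchanged where no value is missing. Under normexp background correction RARB and RAB6B, both with dim signals, reversed to -0.18 and -0.07. The probes with the smallest p on the whole array carried no symbol, and a pair of them is described in the files as relaxin receptor 2, a receptor for insulin-like peptides, which was singled out after its values were seen. Both were well above background in 8 of 8 low-RFI pigs, but only in 7 and 4 of 8 high-RFI pigs, so the size of their difference is uncertain and for the second none is given. The first differed by 2.82 (SE 0.49), with a limma adjusted p of 0.849 for both. Within replicates 1 to 4 the first passed in limma, at 3.95 (adjusted p = 7.3e-04), and within replicates 5 to 8 it did not, at 1.70 (SE 0.67, adjusted p = 0.845).

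**Figure D1:**
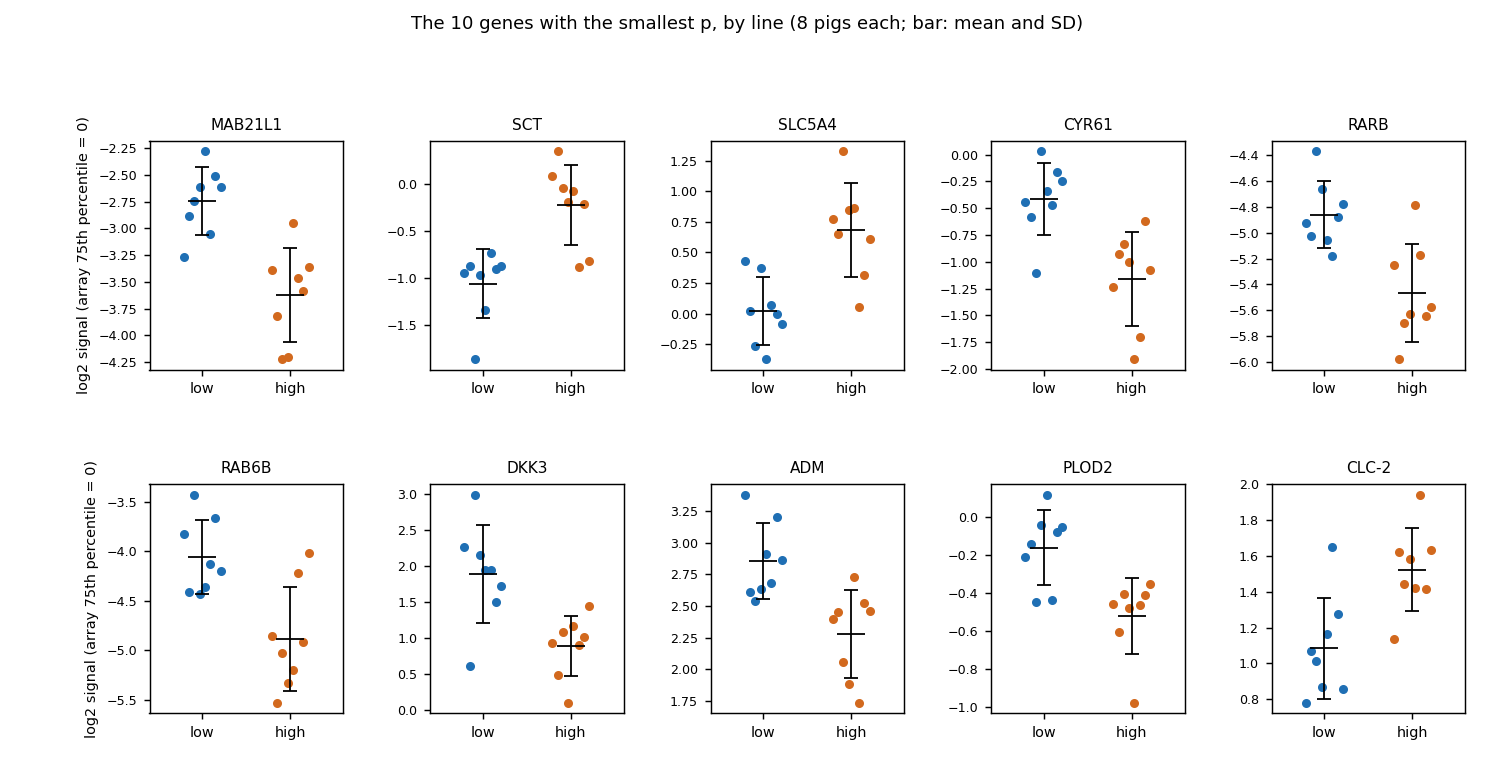
Log2 signal (array 75th percentile = 0) of the 10 genes with the smallest p in low-RFI and high-RFI pigs. Points are the 8 pigs of each line, and bars are the mean and SD. MAB21L1 averaged -2.74 in low-RFI and -3.62 in high-RFI pigs, and none of the 10 genes passed the threshold.

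No gene of fat storage and mobilisation, the main work of this tissue, separated the lines. In the 8 lists of this paragraph 0 members passed in limma over all genes or when adjusted over the list alone. Of 13 fatty acid synthesis genes, FADS1, a fatty acid desaturase, differed by -0.19 (SE 0.10) and ACLY, which supplies cytosolic acetyl-CoA, by 0.26 (SE 0.26). Of 18 triglyceride synthesis and lipid droplet genes, CIDEC, a lipid droplet protein, differed by 0.31 (SE 0.19) and PLIN3 by -0.18 (SE 0.11). Among 11 genes of fatty acid uptake, SLC27A1, a fatty acid transporter, differed by 0.22 (SE 0.12) and LPL, lipoprotein lipase, by 0.20 (SE 0.16). Of 12 lipolysis genes, MGLL, monoglyceride lipase, differed by 0.26 (SE 0.20) and ADRB3 by 0.16 (SE 0.14), the latter reversing to -0.28 under normexp. Of 21 fatty acid oxidation genes, ACAA1 differed by -0.27 (SE 0.14) and ACADSB by 0.23 (SE 0.14). Of 13 cholesterol synthesis genes, CYP51, a sterol demethylase, differed by 0.24 (SE 0.20). Among 16 adipogenesis and adipokine genes, EBF2, a transcription factor of the adipocyte lineage, differed by 0.43 (SE 0.15) and KLF5 by 0.30 (SE 0.28), and KLF5 reversed to -0.12 under normexp. The 12 adipocyte markers had a mean difference of 0.03. In the main fit camera called none of these lists. Its adjusted p was 0.504 for fatty acid synthesis and for lipolysis, 0.930 for lipid droplets and 0.380 for uptake. The camera adjusted p was 0.913 for oxidation, 0.341 for cholesterol synthesis and 0.461 for adipogenesis and for adipocyte markers.

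Lists of oxidative phosphorylation and glycolysis genes averaged higher in low-RFI pigs. The 28 measured oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, had a mean difference of 0.13, with 26 positive and 2 negative (camera adjusted p = 1.5e-04). This call was lost with an estimated correlation (adjusted p = 0.852 with an estimated correlation) and in fry (adjusted p = 0.931). ATP5I and NDUFC1 stood at 0.24 (SE 0.12) and 0.26 (SE 0.13). The 15 glucose uptake and glycolysis genes had a mean difference of 0.18, with 13 positive (camera adjusted p = 0.030), a call lost in the same tests (adjusted p = 0.852 with an estimated correlation and 0.931 in fry). PKM2 and PFKM, which encode pyruvate kinase and phosphofructokinase, stood at 0.54 (SE 0.27) and 0.70 (SE 0.51). In both lists 0 members passed over all genes or when adjusted over the list alone. With slide as a block the shifts were 0.12 (camera adjusted p = 6.0e-05) and 0.18 (0.019). Within slides 1 to 4 they were 0.13, 0.18, -0.04 and 0.22 for oxidative phosphorylation and 0.18, 0.16, -0.08 and 0.46 for glycolysis. Fitted within replicates 1 to 4 they were -0.10 and -0.14, and within replicates 5 to 8 0.37 and 0.50. On low-RFI replicate 8 PFKM lay 3.74 above the mean of the other 7 low-RFI arrays, and the skeletal muscle genes MYL1, TNNT3 and CKM, chosen after their values were seen, lay 12.5, 12.2 and 6.27 above the mean of the other 15. MYL1 and TNNT3 also lay 4.83 and 3.94 above the other arrays on low-RFI replicate 6 and 2.87 and 1.97 on high-RFI replicate 7. Without low-RFI replicate 8 the shifts were 0.08 (camera adjusted p = 0.0593) for oxidative phosphorylation and 0.08 (0.341) for glycolysis. The glycolysis call also ended without low-RFI replicate 4 (0.0605) or 5 (0.0671) and without high-RFI replicate 5 (0.143), 6 (0.119) or 7 (0.0538), with quantile scaling (0.0520) and with array weights (0.160).

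Other lists of energy metabolism were not called in the main fit. The 17 tricarboxylic acid cycle genes averaged 0.06 (camera adjusted p = 0.0892), with IDH3A at 0.22 (SE 0.14) and PC, pyruvate carboxylase, at -0.23 (SE 0.19). Of 10 genes of branched-chain amino acid catabolism, BCKDHA differed by -0.25 (SE 0.13) and DBT by 0.18 (SE 0.21). Of 26 antioxidant genes, SOD2 differed by 0.21 (SE 0.16) and MGST3 by 0.20 (SE 0.15). Among 11 genes of thermogenesis and futile cycles, COX7A1 differed by 0.28 (SE 0.16) and GATM, a creatine synthesis enzyme, by 0.38 (SE 0.22). The 22 insulin, IGF and growth hormone signalling genes averaged 0.05 (camera adjusted p = 0.101), with IGFBP6 at 0.39 (SE 0.19) and IGF2 at 0.30 (SE 0.18). The camera adjusted p was 0.938 for branched-chain amino acids, 0.655 for antioxidant genes and 0.378 for thermogenesis. In these 5 lists 0 members passed over all genes or when adjusted over the list alone.

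Of the immune lists, camera called complement and T and NK cell markers, both lower in low-RFI pigs. The 26 complement and acute inflammation genes averaged -0.27, with 21 negative (camera adjusted p = 0.030). This call was lost with an estimated correlation (adjusted p = 0.852 with an estimated correlation) and in fry (adjusted p = 0.931). CCL2, a monocyte chemokine, stood at -0.68 (SE 0.28) and the interferon-induced chemokine CXCL9 at -1.18 (SE 0.57). The 10 T and NK cell markers averaged -0.37, with 9 negative (camera adjusted p = 0.035), a call lost in the same tests (adjusted p = 0.852 with an estimated correlation and 0.931 in fry). GZMK, a granzyme, stood at -0.64 (SE 0.31) and CD3E, a chain of the T cell receptor complex, at -0.90 (SE 0.49). In both lists 0 members passed over all genes or when adjusted over the list alone. With slide as a block the shifts were -0.27 (0.019) and -0.37 (0.027). Within slides 1 to 4 they were -0.25, -0.61, 0.05 and -0.26 for complement and -0.46, -0.57, -0.44 and 0.01 for T and NK cells. Fitted within replicates 1 to 4 they were 0.12 and 0.02, and within replicates 5 to 8 -0.66 and -0.77. On high-RFI replicate 5 the complement list lay 1.28 above the mean of the other 7 high-RFI arrays. Without that array the shifts were -0.11 (adjusted p = 0.505) and -0.21 (0.439). The complement call also ended without low-RFI replicate 2 (0.0532), 7 (0.0889) or 8 (0.126), and the T and NK cell call without low-RFI replicate 1 (0.0900), 7 (0.115) or 8 (0.126) or high-RFI replicate 4 (0.0641), 6 (0.119) or 7 (0.120). The complement call also ended with array weights (0.264) and without the filter on dim probes (0.0501). That of T and NK cells also ended with quantile scaling (0.0520), array weights (0.379), the filter on all 16 arrays (0.0867), the set block (0.0550) and set and slide (0.0532).

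Other immune lists were not called in the main fit. The 9 genes of MHC class II antigen presentation were all lower in low-RFI pigs by their means (mean difference -0.22, camera adjusted p = 0.0615), with CD74, the invariant chain, at -0.37 (SE 0.19) and SLA-DQA1 at -0.28 (SE 0.21). With slide as a block this list was called (0.033), and within slides 1 to 4 its shift was 0.25, -0.59, -0.25 and -0.27. Camera with an estimated correlation, not run with the slide block, gave an adjusted p of 0.852 for it in the main fit. Of 19 interferon response genes, OASL differed by -0.62 (SE 0.51). The direction of the interferon list changed with the arrays kept. Its mean centred signal was 1.83 on high-RFI replicate 5 and 1.05 on low-RFI replicate 1, against 0.31 or lower on all others. Camera called it higher in low-RFI pigs without high-RFI replicate 5 (0.0205), without 4 arrays (0.0114) and within replicates 1 to 4 (0.0036). Within replicates 5 to 8 camera called it lower (0.0012). In the main fit its camera adjusted p with an estimated correlation was 0.965. AIF1 and TYROBP stood at -0.43 (SE 0.28) and -0.36 (SE 0.24) among 11 macrophage markers, a list called higher in low-RFI pigs within replicates 1 to 4 (0.011) and lower within replicates 5 to 8 (8.0e-04). S100A9 and S100A12 stood at -0.77 (SE 0.46) and -0.81 (SE 0.52) among 7 neutrophil and mast cell markers. Of 6 markers of lymphatic vessels and lymph node stroma, CXCL13 differed by -1.19 (SE 0.61), and by -0.72 without high-RFI replicate 5. MADCAM1 differed by 0.18 (SE 0.14), reversing to -0.11 under normexp. The 3 measured B and plasma cell markers were too few to test as a list, with FCRLA at 0.63 (SE 0.32) and VPREB3 at -0.36 (SE 0.37). The camera adjusted p was 0.677 for interferon response, 0.326 for macrophage, 0.184 for neutrophil and mast cell and 0.885 for lymphatic markers. In these 6 lists 0 members passed over all genes or when adjusted over the list alone.

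Of the called lists, skeletal muscle and skin epithelium markers had the largest mean differences. The 15 skeletal muscle genes averaged 1.12 higher in low-RFI pigs, all 15 positive (camera adjusted p = 1.8e-04). This call was lost with an estimated correlation (adjusted p = 0.852 with an estimated correlation) and in fry (adjusted p = 0.931). CASQ1, a calcium-binding protein of the muscle reticulum, stood at 1.62 (SE 1.04) and ENO3, muscle enolase, at 1.11 (SE 0.87). The 6 skin epithelium genes averaged -1.10, all 6 negative (camera adjusted p = 2.8e-04), a call lost in the same tests (adjusted p = 0.852 with an estimated correlation and 0.931 in fry). CDH1, the epithelial cadherin, stood at -1.60 (SE 0.69) and DSG1, a desmosomal cadherin, at -0.53 (SE 0.23). In both lists 0 members passed over all genes or when adjusted over the list alone. With slide as a block the shifts were 1.10 (1.7e-04) and -1.10 (4.7e-04). Within slides 1 to 4 they were -0.02, 0.11, 0.39 and 3.96 for muscle and -2.33, -1.10, -0.87 and -0.10 for epithelium. Fitted within replicates 1 to 4 they were -0.11 (14 genes) and -0.83, and within replicates 5 to 8 2.29 and -1.38. MYL1, TNNT3 and EPCAM were chosen after their values were seen. On low-RFI replicate 8 MYL1, a myosin light chain, was 12.5 and TNNT3, a troponin, 12.2 above the mean of the other 15 arrays, and without that array the muscle shift was 0.13 (adjusted p = 0.405). On high-RFI replicates 2 and 6 EPCAM, an epithelial adhesion molecule, was 3.98 and 5.80 above the mean of the other 15 arrays, and the epithelial shift was -0.89 (adjusted p = 0.0026) without replicate 2, -0.68 (0.0113) without replicate 6 and -0.37 (0.0815) without both. The epithelial call held without any 1 array.

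**Figure D2:**
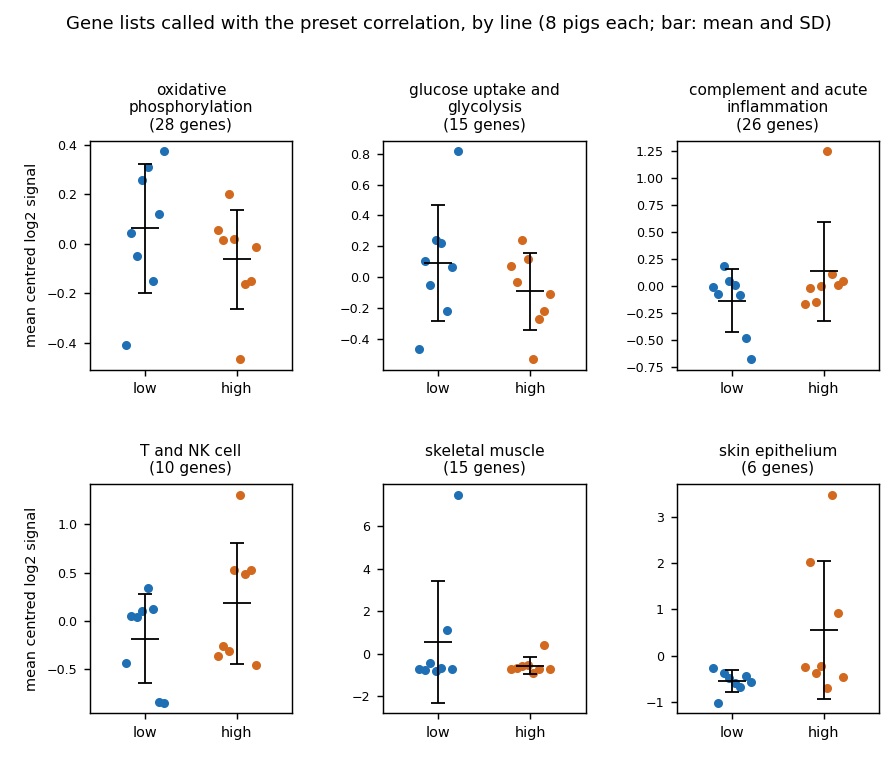
Mean centred log2 signal of the genes of each list that camera called with the preset correlation, in low-RFI and high-RFI pigs. Points are the 8 pigs of each line, and bars are the mean and SD. A single low-RFI pig lies far above all others for skeletal muscle, and without it the muscle shift was 0.13.

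Markers of vessels, stroma, nerve and blood were not called in the main fit. SOX18 and ENG, both endothelial, stood at -0.33 (SE 0.15) and -0.28 (SE 0.14) among 11 markers. CNN1 and MYLK, of smooth muscle contraction, stood at -0.996 (SE 0.66) and -0.39 (SE 0.27) among 8. Of 10 fibroblast and preadipocyte markers, ICAM1 differed by -0.49 (SE 0.19) and DLK1, a preadipocyte factor, by 0.49 (SE 0.19), which reversed to -0.29 under normexp. Of 6 nerve markers, CDH19 differed by 0.46 (SE 0.19), reversing to -0.19 under normexp. The camera adjusted p was 0.184 for endothelial, 0.656 for smooth muscle, 0.101 for fibroblast and 0.547 for nerve markers. Both measured erythroid markers were lower in low-RFI pigs by their means, HEMGN by -0.26 (SE 0.09) and CA1 by -0.34 (SE 0.27). HEMGN was the 1 gene of all lists that passed when adjusted over the list alone, in a list of 2 measured genes, and it did not pass over all genes.

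No list of protein synthesis, protein folding, matrix or proliferation was called in the main fit. The 37 cytosolic ribosomal protein genes averaged 0.03 (camera adjusted p = 0.0615), with RPL13A at -0.17 (SE 0.11) and RPS10 at 0.12 (SE 0.08). MRPL13 and MRPL52 stood at 0.21 (SE 0.20) and 0.08 (SE 0.08) among 12 mitochondrial ribosomal proteins, and PSMC1 and PSMB3 at -0.18 (SE 0.12) and -0.20 (SE 0.16) among 17 proteasome subunits. Of 11 chaperones, HSP90AA1 differed by 0.19 (SE 0.11) and DNAJB1 by -0.21 (SE 0.17). SDF2L1, a chaperone of the endoplasmic reticulum, differed by -0.80 (SE 0.29) and DNAJC3 by -0.20 (SE 0.11) among 12 genes of endoplasmic reticulum stress. Of 24 extracellular matrix genes, DCN, decorin, differed by 0.20 (SE 0.12) and FBN1, fibrillin, by 0.39 (SE 0.26). FOS stood at 1.34 (SE 0.60) and NR4A2 at 0.27 (SE 0.29) among 9 immediate early genes, and NR4A2 reversed to -0.11 under normexp. The mitotic kinases PLK1 and AURKA stood at -0.46 (SE 0.25) and -0.25 (SE 0.18) among 13 cell cycle genes. The clock regulators ARNTL and RORA stood at -0.45 (SE 0.34) and -0.20 (SE 0.16), with 4 genes measured, too few to test as a list. The camera adjusted p was 0.341 for mitochondrial ribosomal proteins, 0.547 for the proteasome, 0.326 for chaperones, 0.117 for endoplasmic reticulum stress, 0.461 for matrix, 0.196 for immediate early and 0.379 for cell cycle genes. In these 9 lists 0 members passed over all genes or when adjusted over the list alone.

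Over all 36 tested lists camera called 6 with the preset correlation, 3 in each direction, and 0 with an estimated correlation, and fry called 0. Without low-RFI replicate 8 camera called 1, and without high-RFI replicate 1 or 3 it called 10. Apart from interferon response, higher in low-RFI pigs without high-RFI replicate 5 (0.0205), lists not called in the main fit passed without 1 array as follows. MHC class II passed, lower in low-RFI pigs, without low-RFI replicate 2 (0.0252), 5 (0.0146) or 6 (0.0474) and high-RFI replicate 3 (0.0230), 4 (0.0311), 6 (0.0157) or 8 (0.0376). Cytosolic ribosomal proteins passed, higher, without low-RFI replicate 3 (0.0145), 4 (0.0019) or 6 (0.0315) and high-RFI replicate 1 (0.0374), 2 (0.0227), 5 (0.0205) or 7 (0.0175). The tricarboxylic acid cycle passed, higher, without low-RFI replicate 1 (0.0122), 3 (0.0252) or 6 (0.0179) and high-RFI replicate 1 (0.0374), 3 (0.0049) or 4 (0.0311). Endoplasmic reticulum stress passed, lower, without low-RFI replicate 3 (0.0382) and high-RFI replicate 1 (0.0374), 3 (0.0442) or 4 (0.0426), and cell cycle, lower, without high-RFI replicate 1 (0.0374) or 3 (0.0438). Fibroblast markers passed, higher, without low-RFI replicate 5 (0.0425) or 7 (0.0210) and high-RFI replicate 8 (0.0490). Insulin and IGF signalling passed, higher, without low-RFI replicate 2 (0.0252) and high-RFI replicate 5 (0.0429). The 6 lists, oxidative phosphorylation, glycolysis, complement, T and NK cells, skeletal muscle and skin epithelium, kept the direction of their shift under normexp, quantile and median scaling. Normexp also moved the median difference over all probes to -0.12, so the shifts under it are relative to that. The sign of the mean difference differed from that of the median or of the camera direction in 4 tested lists. Mean and median were -0.03 and 0.01 for antioxidant genes, 0.01 and -0.01 for lipid droplet genes, 0.04 and -0.01 for extracellular matrix and -0.12 and -0.03 for lymphatic markers, and camera's direction was up in all 4.

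Lists outside these 6 were also called by camera in other fits, some in opposite directions. Fatty acid oxidation was lower in low-RFI pigs within replicates 1 to 4 (adjusted p = 0.0237) and higher within 5 to 8 (0.0056). The proteasome was lower within 1 to 4 (0.0114) and without 4 arrays (0.0114), and higher within 5 to 8 (0.0215). Extracellular matrix and lymphatic markers were higher within 1 to 4 (0.0109 each) and lower within 5 to 8 (0.0407 and 0.0341). Fibroblast markers were higher within 1 to 4 (2.5e-04). Within 5 to 8 the tricarboxylic acid cycle (1.7e-05), mitochondrial (0.0024) and cytosolic (0.0183) ribosomal proteins, adipocyte markers (0.0092), fatty acid synthesis, antioxidant genes and chaperones (0.0265 each) were higher, and endoplasmic reticulum stress (0.0078) and cell cycle (0.0172) lower. Under normexp cytosolic (7.1e-10) and mitochondrial (0.0030) ribosomal proteins, the tricarboxylic acid cycle (2.3e-05), matrix (0.0047), adipocyte markers (0.0160), fatty acid uptake and chaperones (0.0221 each), fatty acid synthesis and insulin and IGF signalling (0.0223 each), antioxidant genes (0.0277) and the proteasome (0.0372) were higher, and nerve markers (0.0233) lower. Array weights called insulin and IGF signalling (0.0391) and cytosolic ribosomal proteins (0.0045) higher and neutrophil and mast cell markers (0.0482) lower. Cytosolic ribosomal proteins were higher and MHC class II lower with median centring (0.0183 and 0.0373), the deposited value table (0.0302 and 0.0372) and the mean of all probes of a gene (0.0088 and 0.0435), and MHC class II was lower with the replicate block (0.0132).

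A division that the labels do not describe was larger than that between the lines. Replicates 5 to 8 of both lines had higher signals than replicates 1 to 4 for CLDN3, a tight junction protein, by 4.01 (SE 0.72, limma adjusted p = 0.0080), and for UCP2, a mitochondrial carrier, by 1.48 (SE 0.21, adjusted p = 0.0062). They had lower signals for KLKB1, plasma prekallikrein, by -3.21 (SE 0.58, adjusted p = 0.0080), and for MYOC, myocilin, by -1.91 (SE 0.29, adjusted p = 0.0062). With line in the limma fit, 1662 of 32097 probes (640 higher and 1022 lower in replicates 5 to 8) and 324 of 4631 genes passed, 217 of them lower in replicates 5 to 8. This comparison was chosen after the arrays had been seen to divide in this way. Each slide held arrays of both sets, and with slide in the fit 1600 probes passed. Within high-RFI pigs 1468 probes passed and within low-RFI pigs 0 in limma, with 2755 at an unadjusted p under 0.05 in the latter. The difference between the lines in this contrast was 0 probes by the interaction term, with 2186 at an unadjusted p under 0.05. The set accounted for 53.9% of the first principal component and the line for 9.06%, a share favoured by picking the division after it was seen. On components 2 and 3 the set accounted for 10.3% and 1.55% and the line for 2.20% and 0.16%. The order was the other way on components 4, 5 and 6, with 14.6%, 9.89% and 13.5% for the line and 0.0054%, 6.53% and 0.0021% for the set. Leaving out low-RFI replicate 3 raised the count to 4780 probes. It was 621, 633, 970 and 839 without low-RFI replicate 2, 4, 5 or 7, and 800, 952, 683, 602, 1053, 738 and 765 without high-RFI replicate 1, 2, 3, 4, 6, 7 or 8. With the set as a block in the comparison of the lines, 0 probes and 0 genes passed in limma, with 1618 probes at an unadjusted p under 0.05.

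**Figure D3:**
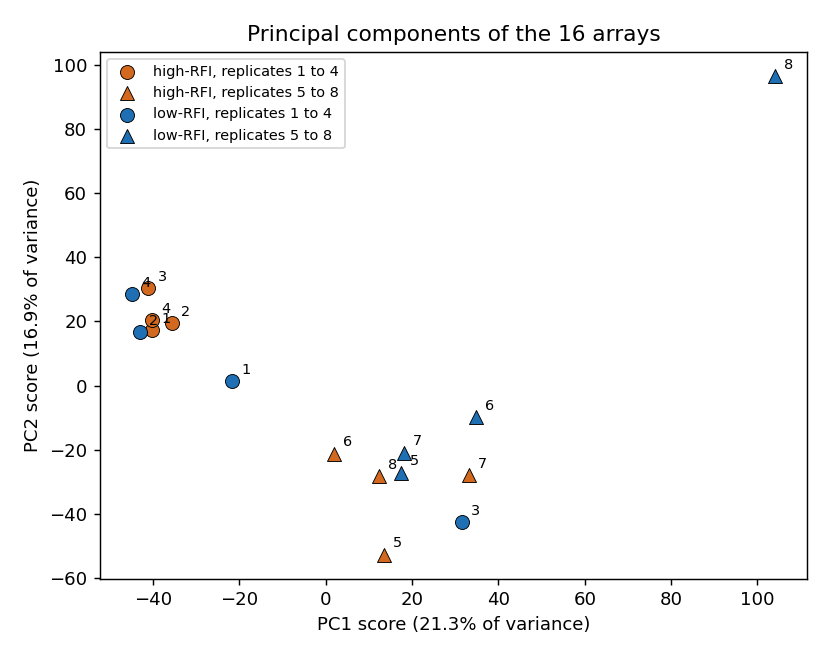
Scores of the 16 arrays on the first and second principal components, with the percent of variance of each on the axis labels. Points are arrays, coloured by line, with circles for replicates 1 to 4 and triangles for replicates 5 to 8. Circles and triangles part along the first component, which carries 21.3% of the variance, except for low-RFI replicate 3, a circle among the triangles.

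**Figure D4:**
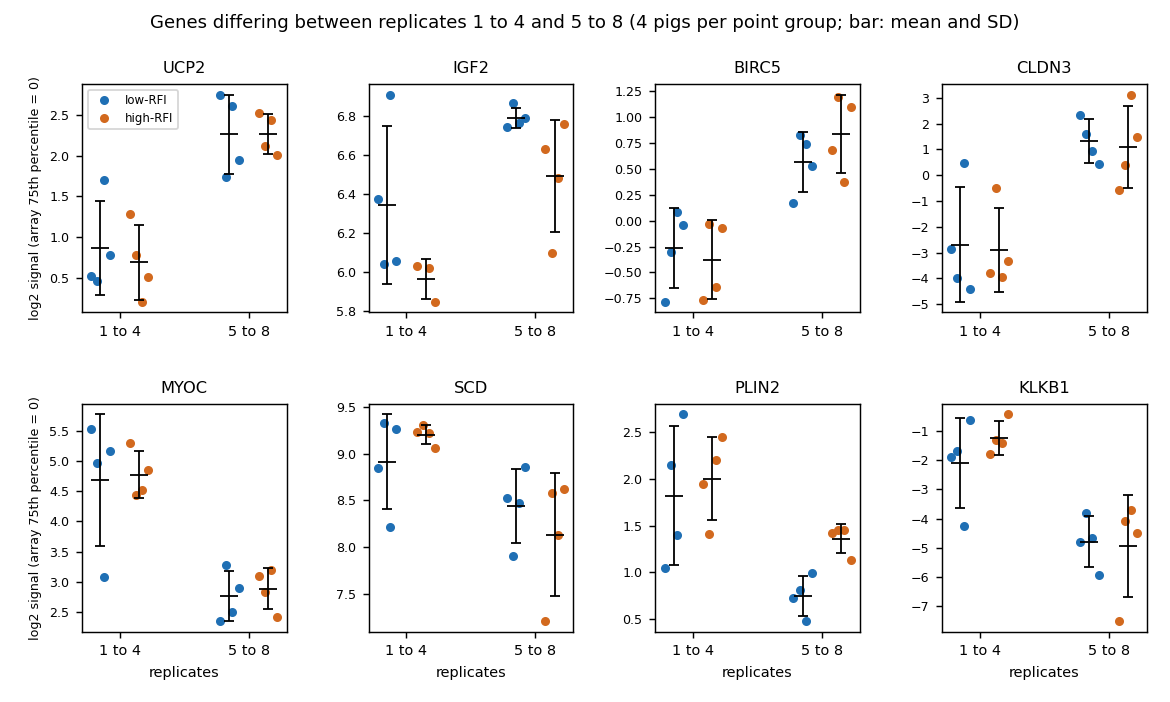
Log2 signal (array 75th percentile = 0) of 8 genes in replicates 1 to 4 and 5 to 8 of each line. Points are pigs, 4 per line and set except 3 high-RFI pigs for IGF2 in replicates 1 to 4, and bars are the mean and SD. UCP2, IGF2, BIRC5 and CLDN3 were higher and MYOC, SCD, PLIN2 and KLKB1 lower in replicates 5 to 8 of both lines.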

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

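The fits without high-RFI replicates 2 and 6 together and without 4 arrays were chosen after results were seen, whereas the slide block and leaving out single arrays were planned. For each named gene, each tested list and some measures of array quality, such as the median signal, each line was examined. The highest or lowest of its 8 arrays was compared with the rest by its gap to the nearest array over the range of all 8. Chance marks about 1 in 20 groups, so 12.3 of the 246 groups would be expected, and 18 had an array apart, 9 for genes and 9 for lists. High-RFI replicate 5 was the array apart in 7 of them, low-RFI replicate 8 in 5 and low-RFI replicate 1 in 3. Values below are the array minus the mean of the other 7 arrays of its line.

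The skeletal muscle, oxidative phosphorylation and glycolysis lists were higher in low-RFI pigs, and low-RFI replicate 8 lay 7.93 above the other low-RFI arrays in the muscle list, 7.94 in CASQ1, 7.36 in ENO3 and 3.74 in PFKM. Slide was argued against by the design alone, since every slide held 2 arrays of each line. With slide as a block the muscle shift was 1.10 (camera adjusted p = 1.7e-04). This balance leaves a difference nearly unchanged by the block, so that result adds no support. Within slides 1 to 4 the muscle shift was -0.02, 0.11, 0.39 and 3.96, and low-RFI replicate 8 lay on slide 4. Without low-RFI replicate 8 the muscle shift went from 1.12 to 0.13 (adjusted p = 0.405) and that of glycolysis from 0.18 to 0.08 (0.341), so skeletal muscle RNA in that sample may account for both. The glycolysis call ended in 6 of the 16 fits without 1 array, so its loss is not particular to low-RFI replicate 8. On that array MYL1, ACTA1 and TNNC2, chosen after their values were seen, lay 12.5, 5.02 and 1.71 above the mean of the other 15 arrays, MYL1 at 7.99 and ACTA1 at 8.97, and of the 24 genes of the list 15 were measured, none of them in another list. For oxidative phosphorylation the shift went from 0.13 to 0.08 (adjusted p = 0.0593), and without low-RFI replicate 8 and high-RFI replicates 2, 5 and 6 it was -0.0034 (0.923), so muscle RNA, the other arrays and a difference between the lines cannot be told apart.

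The skin epithelium, complement and T and NK cell lists were lower in low-RFI pigs. Without high-RFI replicate 5, where the complement list lay 1.28 above the other high-RFI arrays and SAA3, chosen after its values were seen, and CXCL9 lay 5.56 and 3.51 above the mean of the other 15 arrays, the complement shift went from -0.27 to -0.11 (adjusted p = 0.505), and inflammation in that pig may account for it. The complement call also ended without other single arrays, in 4 of 16 such fits in all. Without high-RFI replicate 5 the shift of T and NK cells went from -0.37 to -0.21 (adjusted p = 0.439), and without that array, low-RFI replicate 8 and high-RFI replicates 2 and 6 it was -0.08 (0.844), so inflammation there, the other arrays and a difference between the lines cannot be told apart. On high-RFI replicates 2 and 6 the gland genes LTF and SCGB1D1, chosen after their values were seen, reached 4.13 and 4.63 on the former and 5.93 and 2.40 on the latter, and without both arrays the epithelial shift went from -1.10 to -0.37 (adjusted p = 0.0815), which by the bound set beforehand points to epithelial or gland tissue in them. That reading was changed to open after the result was seen, because without low-RFI replicate 8 and high-RFI replicates 2, 5 and 6 the list was still called at -0.47 (adjusted p = 0.0114). High-RFI replicate 7 stayed in that fit, with a mean centred signal of the list of 0.92, against -0.22 or lower on the other high-RFI arrays kept. The list was not tested without this array as well, so epithelial tissue there and a difference between the lines cannot be told apart.

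On high-RFI replicate 5 the other values apart were 2.04 for the interferon response list, 3.33 for OASL, 1.28 for MHC class II, 1.03 for CD74, 0.58 for RPL13A and -0.53 for PLOD2. Low-RFI replicate 1 stood apart in the interferon response list by 1.25, in OASL by 2.36 and in PSMC1 by -0.50. Low-RFI replicate 8 stood apart in the thermogenesis list by 2.04, high-RFI replicate 7 in the muscle list by 1.11, low-RFI replicate 4 in the immediate early genes by 0.90 and low-RFI replicate 2 in insulin and IGF signalling by -0.33. No explanation of these was tested.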

How the results depend on the processing

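The fits without 4 arrays (low-RFI replicate 8 and high-RFI replicates 2, 5 and 6), with a sample set block, with set and slide, and within either set of replicates were chosen after seeing the data. The count of genes stayed at 0 in limma under all alternatives except the threshold of an unadjusted p under 0.01, which gave 25 genes and 180 probes by its construction. The count of probes was 0 to 1 over the fits without 1 array, the 1 coming without low-RFI replicate 4, and 5 within replicates 1 to 4. The count of lists, 6, was 18 under normexp, 0 with an estimated correlation, 0 in fry, 3 without the 4 arrays and 21 within replicates 5 to 8. Without 1 array it ranged from 1 (without low-RFI replicate 8) to 10 (without high-RFI replicate 1 or 3). With the replicate block, run although the numbers do not pair the pigs (correlation of pairs -0.29 to 0.32, own number best in 1 of 8), 0 probes, 0 genes and 7 lists passed. The scan block was not run because each slide was 1 scan.

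Of the adjusted p of the 6 lists without 1 array, the ranges were 4.8e-09 to 0.0593 for oxidative phosphorylation, 7.2e-04 to 0.341 for glycolysis, 0.0032 to 0.505 for complement, 0.0032 to 0.439 for T and NK cells, 1.4e-05 to 0.405 for muscle and 2.4e-05 to 0.0113 for skin epithelium. Calls ended with quantile scaling for glycolysis and for T and NK cells (0.0520 each), with array weights for glycolysis (0.160), complement (0.264) and T and NK cells (0.379), without the filter on dim probes for complement (0.0501) and with all 16 arrays well above background for T and NK cells (0.0867), where skin epithelium had under 5 genes left and was not tested. The T and NK cell call also ended with the set block (0.0550) and with set and slide (0.0532), and the skin epithelium call within replicates 1 to 4 (0.0863). Camera's direction reversed within replicates 1 to 4 for oxidative phosphorylation and glycolysis (0.128 each), complement (0.331), T and NK cells (0.825) and muscle (0.834). Without the 4 arrays camera's direction reversed for glycolysis (0.782), complement and muscle (0.931 each), with mean shifts of -0.0348, -0.0064 and -0.0256, so that the mean of complement kept its sign. There the oxidative phosphorylation mean turned to -0.0034 while camera's direction stayed up (0.923), and the T and NK cell call ended (0.844).

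For 83 named genes under 32 settings, 2617 of 2643 differences kept their sign and 26, of 22 genes, reversed. Under normexp these were RARB -0.18, RAB6B -0.0727, ADRB3 -0.28, KLF5 -0.12, NR4A2 -0.11, DLK1 -0.29, CDH19 -0.19 and MADCAM1 -0.11. Within replicates 1 to 4 they were CIDEC -0.0947, LPL -0.0242, IDH3A -0.16, ATP5I -0.0406, PFKM -0.0688, DBT -0.17, MRPL13 -0.13, MRPL52 -0.0276, COX7A1 -0.12, OASL 0.34 and CD3E 0.11. Within replicates 5 to 8 they were KLF5 -0.13, FBN1 -0.23, NR4A2 -0.15, MADCAM1 -0.0152, PSMC1 0.10 and VPREB3 0.44, and without the 4 arrays OASL 0.0309. Fits within a set or without 4 arrays hold fewer samples, and otherwise the cause was not tested. Signal over background limits the dim probes: the filter left 32216 of 43603 probes, and without it 0 probes passed in limma (1779 at an unadjusted p under 0.05).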

Other observations

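The comparison of replicates 5 to 8 with 1 to 4 and its tests were chosen after the arrays had been seen to divide in this way, and the tests of other splits for 0 probes and 0 genes after those counts were known. Of 13 cell cycle genes 3 passed in limma over all genes and 10 when adjusted over the list alone, all 3 of the former higher in replicates 5 to 8. Camera called the list at 0.72, and the call was lost with an estimated correlation (adjusted p = 0.774 with an estimated correlation). BIRC5, an inhibitor of apoptosis active in mitosis, rose by 1.02 (SE 0.17, adjusted p = 0.0062), and CCNB2, a mitotic cyclin, by 1.07 (SE 0.31, adjusted p = 0.049). Of 22 insulin and IGF signalling genes 4 passed over all genes and 10 over the list alone, all 4 of the former higher: IGFBP3 by 0.83, IGFBP5 by 0.80, EIF4EBP1 by 0.55 and IGF2 by 0.48. That list itself was not called (camera adjusted p = 0.083, 0.929 with an estimated correlation and 0.344 in fry). The imprinted genes MEST and NNAT were higher by 1.88 and 1.25, the lipid sensor NR1H3 by 0.52 and UCP2 by 1.48.

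Single genes of fat storage and immunity passed in both directions. SCD, a fatty acid desaturase, changed by -0.77 (SE 0.22, adjusted p = 0.049), PLIN2, a lipid droplet protein, by -0.86, AQP7, the glycerol channel, by -0.67 and ADIPOR2 by -0.48. LYZ, lysozyme, changed by -1.88, S100A9 by -1.27, IL6 by -0.89 and TLR4 by -0.72, whereas C4A, of the complement system, and PGLYRP1, a bacterial recognition protein, were higher by 1.42 and 2.31. The lists of fatty acid synthesis (1 of 13 passing, camera adjusted p = 0.175), lipid droplets (1 of 18, 0.782) and complement (3 of 26, 0.637) were not called. The secreted MYOC and KLKB1 changed by -1.91 and -3.21. Camera called 6 of 36 lists: cell cycle 0.72 (adjusted p = 8.3e-08), cytosolic ribosomal proteins 0.06 (0.0063), interferon response 0.39 (0.012), skeletal muscle 1.31 (0.012), branched-chain amino acids -0.36 (0.047) and neutrophil and mast cell markers -0.83 (0.018). With an estimated correlation 0 were called (adjusted p = 0.774 with an estimated correlation for cell cycle and for neutrophil and mast cell markers), and fry called 2, cell cycle (0.0472) and neutrophil and mast cell markers (0.0230). The skeletal muscle shift includes low-RFI replicate 8.

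The division of replicates 1 to 4 from 5 to 8 gave 1653 probes in limma without other terms. It was argued not to come from slide, since both sets lay on every slide in equal number. That balance leaves the differences nearly unchanged by a slide term, so the 1600 probes that passed with slide and line in the fit add little. The count of splits (1 of 100, the real one, gave as many, and the highest other gave 23) excludes nothing, because the division was picked after it was seen. Array brightness stays open: the share of spots well above background was 75.3% and 72.9% in the sets (exact permutation p = 0.168), and the bound set beforehand, which took such a p as evidence against, was dropped after the result because a p over the threshold does not show equal values. With brightness as a covariate 808 of 1662 probes passed, which by the bound set beforehand would count for brightness, but this was changed to open afterwards because leaving out 1 array lowered the count to as few as 602. A different share of adipocytes cannot be told apart from other causes, since 1 of 4 cell type lists shifted against the adipocyte list (T and NK cells 0.16, SE 0.28, adipocytes -0.12, SE 0.10) and no shift exceeded 2 SE. The labels give no group for this division, so no biological explanation was tested, and age, litter, sex or sampling may lie behind it.

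Low-RFI replicate 3 lay nearer the mean of replicates 5 to 8 at 4221 of 4780 probes (88.4%). These 4780 probes are those that passed in limma without it. For the other arrays of replicates 1 to 4, each left out in the same way, the share nearer replicates 5 to 8 was 6.15% to 42.2%. Within low-RFI pigs 157 probes passed in limma without low-RFI replicate 3 and 0 with it, with 2755 at an unadjusted p under 0.05 in the latter.

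The same 100 splits of the arrays, the real one included, served for the line. All 100 gave at least 0 probes and 0 genes, so these counts exclude nothing, and the highest others, 1653 probes and 344 genes, came from the division of the replicates. For lists, 76 of 100 splits gave at least 6, the highest other gave 26, and chance cannot be excluded for the count of 6. Over the 98 random splits the highest counts were 23 probes and 5 genes, and 3 splits gave any probe.

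Some genes chosen after their values were seen lay far apart on single arrays. ALB, serum albumin, was 0.85 on low-RFI replicate 3 and 1.25 on high-RFI replicate 8, and -2.62 or lower on the other 14. TTR was highest on the same arrays, at -0.71 and -1.10. HOXA11 ranged from -8.27 to 1.71 over the 16 arrays. The genes more than 4-fold above the median of the other arrays numbered 81 on low-RFI replicate 8, 66 on high-RFI replicate 5 and 49 on high-RFI replicate 6.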
